A study of Triticum aestivum with 2 samples.

How the data were processed

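The series holds 2 degradome libraries from spikes of a thermosensitive genic male sterile line of bread wheat, 1 from cold-treated plants and 1 from control plants. A degradome library captures the 5′ ends of polyadenylated RNA fragments, so that a tag begins where a transcript was cleaved or had decayed. Per the labels' protocols, about 20 spikes were taken per stage at anther lengths of 1.5, 2.2 and 3.0 mm, RNA was extracted with TRIzol, and RNA of the 3 stages was mixed within each condition before library construction. Samples were grouped by the treatment given in the labels.

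Each deposited file lists distinct tag sequences with their length and their raw tag count, per the file headers. Identical sequences had been collapsed by the authors, and each sequence stood in 1 row per library with a whole-number count. The read cleaning, any removal of ribosomal RNA and the tool versions are not given in the sources used here. Tags carried no gene names and no genome sequence was used here, so tags and sites are reported by sequence. The planned analyses that needed transcripts, namely gene-level tags, gene lists and the position of 5′ ends along transcripts, were not run.

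The cold library held 26387851 tags of 11132526 distinct sequences and the control library 35477509 tags of 14363576 distinct sequences. Values were scaled to the library total and are given as RPM, the usual unit of tags relative to sequencing depth. A count of 0 allows up to 3 counts, which is 0.114 RPM in the cold library and 0.0846 in the control library. There was 1 library per group, so no difference has a replicate check, no test across conditions was possible and no p-value is given. Each cold/control ratio has an exact (Clopper-Pearson) 95% interval from the binomial split of the pair of counts. Reads amplified by PCR without molecular identifiers are not independent molecules, so the intervals and floors cover counting error only and compare these libraries, not the conditions.

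A 5′ end was defined as the first 18 bases of a tag, which joins tags of different length that start at the same position. The sequences of 30 plant small RNAs were written down before the data were examined, from general knowledge and not from a database. For each, the end left by slicing opposite small RNA bases 10 and 11 was counted. It was taken as the tags that start with the reverse complement of bases 1 to 10. The background was the same count for 1000 dinucleotide-preserving shuffles of each small RNA. The rule fixed before the data were examined named each small RNA with at least 20 tags over both libraries and a count above 99% of its shuffles. The same rule named the 5 most abundant tags of each library and the leading tag of each named small RNA. For genes, which could not be assigned, it took features with at least 50 tags over both libraries whose interval lay wholly above 2 or below 0.5, and named the 12 largest and 12 smallest ratios, and it was applied here to single 5′ ends.

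Both the comparison of single 5′ ends and the rebuilding of target sites were added after the data were seen, in place of the planned work on transcripts. Sites were rebuilt by walking upstream from each end of at least 10 tags through overlapping 16-base words found at least 2 times in the pooled libraries. A mismatch counted 1 point and a G:U pair 0.5 points, with at most 2.5 points over small RNA bases 1 to 10, at most 4 points in all and no mismatch at base 10. The path with the fewest points was kept, so a rebuilt site can join tags of related transcripts. The background was 100 shuffles of each small RNA. Random sets of ends, 10000 per small RNA, were matched on count, or on count, GC content and first base.

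The 5′ end rule, the cut-end rule, the rebuilding of sites and the removal of a GC trend were tested on simulated data. The overlap of libraries, the random sets and the matches to listed proteins and ribosomal RNA were not. Known changes were given to some of the 114183 ends of the comparison of cold with control. The rule recovered 2 of 66 ends changed 2-fold, 56 of 67 changed 4-fold and 67 of 67 changed 8-fold, called 0 of 113983 unchanged ends, and its intervals held the simulated ratio for 96.2% of ends. With shuffled sequences in the place of the small RNAs, 3 of 600 passed the cut-end rule, and 30 of 30 passed after 2000 tags were added. Planted sites were recovered in 30 of 30 simulated transcripts without mismatches and in 30 of 30 with 2 changed bases. All planted sites lay within the penalty limit, so this check does not show how often a real site is missed. Sparse overlaps can hide a site, since miR171 had 0 sites at the main settings and 1 with overlaps seen once allowed. Alternatives for scaling, tag length, match length, mismatches, weighting and count minimums were run, as were alternatives for the penalty and the cut window. Lists of 9 plastid, 4 mitochondrial and 8 cytosolic or nuclear proteins, with short stretches of ribosomal RNA, were written by hand from general knowledge for the closing section. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.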

Results

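RNA cleavage was profiled in spikes of a thermosensitive genic male sterile wheat line, a line whose pollen fertility depends on temperature, with and without cold treatment. The series title places the work in the study of small RNA-mediated responses to cold. Each condition was represented by 1 degradome library made from RNA mixed over 3 anther stages, from the formation of secondary sporogenous cells to meiosis. The cold library held 26387851 tags and the control library 35477509, and there were no replicates.

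Both libraries consisted mainly of tags of 20 and 21 bases. Tags of 20 bases made up 52.9% of the cold library (exact 95% interval 52.91 to 52.94%) and 59.8% of the control library (59.82 to 59.85%). Tags of 21 bases made up 43.1% and 37.6%, respectively. G was the least frequent first base, at 18.6% of cold tags and 18.3% of control tags. The mean GC content of the first 18 bases was 47.0% in the cold library and 47.6% in the control library. Sequences seen once were 67.1% of the distinct sequences in the cold library and 65.4% in the control library.

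The libraries shared 4842565 distinct sequences, which were 43.5% of those in the cold library and 33.7% of those in the control library. The shared sequences held 70.2% of cold tags and 64.5% of control tags. To set this against sampling, the control library was compared with the cold library at the depth of a random split of the cold library into equal parts. At that depth, 33.2% of the distinct sequences of the cold library were shared with the control library, against 37.2% between the parts of the cold library itself.

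The most abundant tags took a larger share of the cold library. The 100 most abundant tags made up 3.41% of cold tags and 1.32% of control tags. The leading cold tag, TACCTGGTTGATCCTGCCAG, was counted 148242 times in the cold library and 29719 times in the control library, an RPM ratio of 6.71 (6.62 to 6.79). Its form that was 1 base longer, TACCTGGTTGATCCTGCCAGT, had a ratio of 10.8 (10.55 to 11.001). The tags CCACACGACTCTCGGCAACGG, CACACGACTCTCGGCAACGG and CATCGAGTAGACCCTGTTAT, also among the 5 most abundant in the cold library, had ratios of 4.33, 3.17 and 4.42. The leading tag of the control library, CACGACTCTCGGCAACGGAT, was counted 46022 times in the cold library and 56336 times in the control library, a ratio of 1.10 (1.08 to 1.11).

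Which small RNAs left cleaved ends in these spikes, and whether those ends differed between the libraries, was addressed with the cut ends of 30 small RNAs. The ends expected from slicing by miR2275, which triggers phased small RNAs in grass anthers, were more frequent in the cold library, with 1436 tags against 752 and a ratio of 2.57 (2.35 to 2.81). Cut ends of miR319, which targets TCP transcription factors, had a ratio of 1.21 (1.07 to 1.36). Ends of 2 small RNAs of the auxin pathway were less frequent in the cold library. The ratio was 0.722 (0.685 to 0.760) for miR160, which targets auxin response factors, and 0.734 (0.654 to 0.822) for miR393, which targets the TIR1/AFB auxin receptors.

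For miR171, tasiR-ARF and miR394 the intervals included 1. miR171, which targets GRAS transcription factors, had a ratio of 1.08 (0.937 to 1.25). The trans-acting small RNA tasiR-ARF, directed against other auxin response factors, had 1.06 (0.958 to 1.18). miR394, which targets F-box proteins, had 1.03 (0.941 to 1.12). Of the 30 small RNAs, these 7 passed the rule of at least 20 tags and more than 99% of shuffles. Their counts over both libraries ranged from 764 tags for miR171 to 6353 for miR160, against shuffle medians of 27 and 32 tags. The other 23 did not pass, and 3 of these had under 20 tags. Failing the rule does not show that a small RNA left no cleaved ends, since the exact match depends on the listed sequence.

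For 6 of the 7 small RNAs, the cut was the position of the paired stretch at which most tags began. The 7 had been named for a high count at the cut, and other positions counted only exact matches to the full complement. Such a peak therefore does not by itself show slicing. For miR160, 6353 tags began at the cut, while the other positions had between 3 and 101 tags each. The peak was less sharp for tasiR-ARF, with 1446 tags at the cut and 1024 tags 1 base upstream. miR171 was the exception, since 3106 tags began 3 bases upstream of the cut and 764 at it. The upstream ends had a ratio of 2.22 (2.07 to 2.39). They are not part of the miR171 ratio given above, which covers the cut expected from the listed sequence alone.

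**Figure D1:**
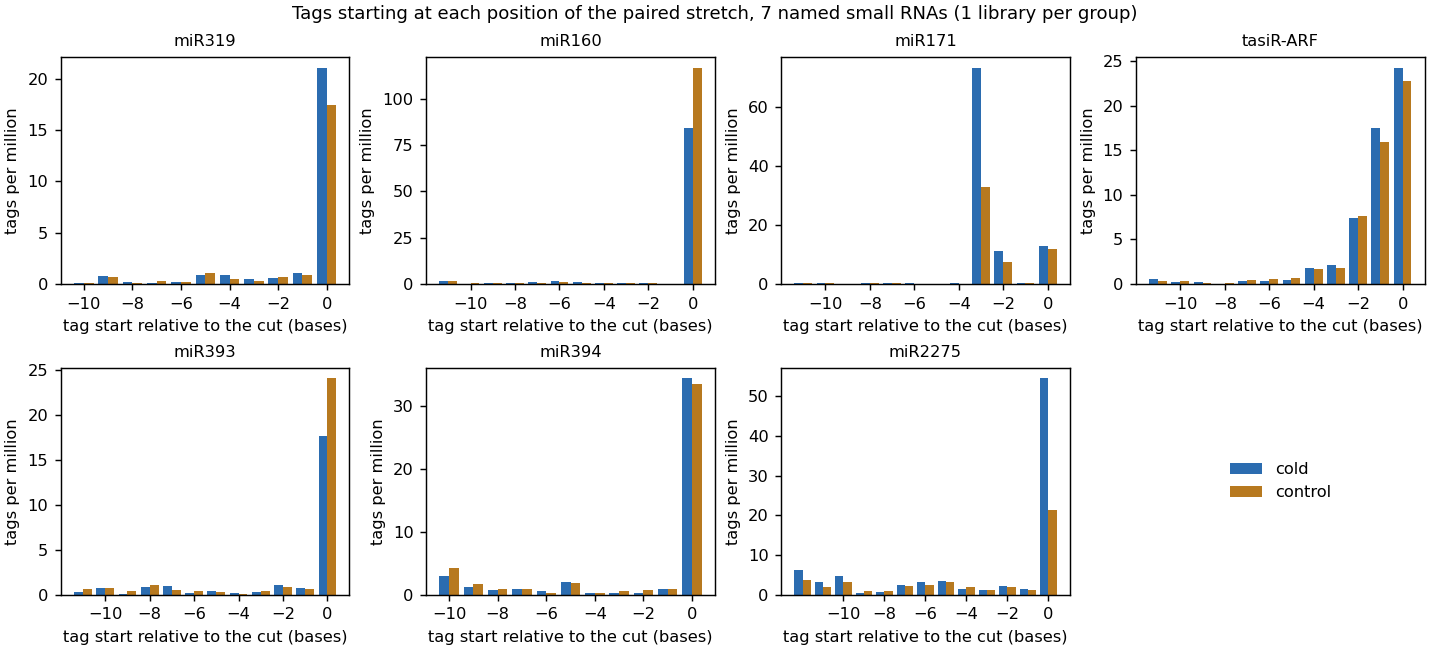
Tags in RPM (vertical axes, from 0) that began at each position of the stretch paired with each of the 7 named small RNAs, with the position in bases relative to the expected cut (0) on the horizontal axes; blue bars are the cold library and brown bars the control library, 1 library each. The cut position holds the highest bar for all but miR171, whose highest bar lies 3 bases upstream.

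For 5 of the 7 small RNAs a leading end held at least 83.3% of the tags. For miR160, the tag GAGCCAGGCATGCTCAATTTG was counted 1499 times in the cold library and 2834 times in the control library, and its end held 91.4% of the miR160 tags. Without that end the direction turned, with a ratio of 1.34 (1.13 to 1.59). The tag TTCAGTCCAATTCGCAGCCGC led for miR319 with 430 cold and 463 control tags, and without its end the ratio was 0.913 (0.636 to 1.30). For miR393, led by TCCCTTTGGATGTCGTCGTGC with 333 and 579 tags, the ratio without the leading end was 0.739 (0.553 to 0.980). With each distinct tag counted once, none of the 30 small RNAs passed the rule, and the ratios of miR160 and miR319 were 1.13 (0.696 to 1.82) and 0.916 (0.505 to 1.63), with intervals that included both 1 and the values above. The miR319 interval also included 1 with 1 mismatch allowed and in tags of 20 or of 21 bases alone. The leading tags of miR171, tasiR-ARF and miR394 were GGCTCAATCACCAGCTTCCC (206 cold and 289 control tags), AGGTCAAGAATTATTGGGTT (223 and 271) and AGAATGCCAAATATCTGGTGC (713 and 911).

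The miR2275 signal was spread over many ends. Its leading tag, GGAAACCAAATCGACTTGTAT, was counted 274 times in the cold library and 110 times in the control library, and its end held 25.4% of the miR2275 tags. Of the 32 miR2275 ends with at least 10 tags, 29 had a ratio above 1. Random sets of ends matched on count gave ratios from 0.770 to 1.52 in the central 95% of 10000 sets, and 0% of sets reached that of miR2275. The miR160 ratio was lower than in each of the 10000 sets matched to it, whose central 95% ran from 0.860 to 5.37. These sets had 4 ends each, and the leading end held 91.4% of the miR160 tags. The sets thus compared mainly that single end with ends of similar count. For miR319 and miR393 the values lay within the central 95% of such sets, which ran from 0.517 to 5.95 and from 0.546 to 5.29.

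Rebuilding the upstream part of the sites from overlapping tags gave paired stretches for 22 of the 30 small RNAs, and 7 passed the same rule. Ends at sites of miR169, which targets nuclear factor Y subunit A, were less frequent in the cold library, with 483 tags against 1060 and a ratio of 0.613 (0.549 to 0.683). This held at each of the 4 miR169 ends, with ratios from 0.536 to 0.690 and intervals below 1. By cut ends, where miR169 did not pass the rule, it had 44 cold and 59 control tags and a ratio of 1.003 (0.663 to 1.51). The miR160 site AGGCATACAGGGAGCCAGGCA had a ratio of 0.678 (0.642 to 0.716), and the miR393 site AGACAATGCGATCCCTTTGGA, found at 3 ends, had 0.732 (0.650 to 0.822). The ends of this miR393 site differed, at 0.733 (0.646 to 0.830), 0.562 (0.348 to 0.886) and 1.04 (0.604 to 1.76). The miR160 site is the leading cut end of miR160, and the miR393 ends are also cut ends of miR393. Their tags were thus counted in both measures, so the rebuilt-site ratios of these small RNAs are not a second measurement. The ratio was 1.28 (1.08 to 1.50) over 5 ends of miR172, which targets APETALA2-like transcription factors, and 267 of its 294 cold tags came from the site CCGCAGCATCATCACGATTCC. Its cut ends did not pass the rule and had a ratio of 1.06 (0.784 to 1.42). At 11 ends of tasiR-ARF the ratio was 1.23 (1.11 to 1.37), whereas the interval of its cut-end ratio included 1. Single tasiR-ARF ends ranged from 0.852 (0.639 to 1.13) to 2.59 (1.61 to 4.25).

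The most abundant rebuilt site was CTGGGATGAAGCCTGGTCCGG of miR166, which targets class III homeodomain-leucine zipper transcription factors. It had 3384 cold and 4496 control tags and a ratio of 1.01 (0.968 to 1.06). Its 3 ends differed, at 1.06 (1.003 to 1.12), 0.993 (0.897 to 1.10) and 0.743 (0.637 to 0.866). The miR167 site TAGATCAGGCTGGCAGCTTGT had a ratio of 0.792 (0.612 to 1.02). With these settings no site was rebuilt for miR2275, miR319 or miR171, and the 1 site of miR394, with 4 cold and 9 control tags, did not pass. With overlaps seen once allowed, miR171 passed with 1 site of 337 cold and 416 control tags, while miR319 had 5 sites and miR2275 had 1 and neither passed. miR394 did not pass there either, with 849 and 1102 tags. In all 5 small RNAs passed in that setting, and miR167, miR172 and tasiR-ARF no longer did. The 1 miR2275 site had 10 cold and 17 control tags, a ratio of 0.791 (0.324 to 1.83), and 3 sites found with the cut allowed 1 base to either side had 12 and 27 tags, a ratio of 0.598 (0.276 to 1.22). The miR2275 value of 2.57 thus rested on the match of 10 bases. At a penalty of at most 3, miR169 and miR172 had 0 sites and 6 small RNAs passed, with miR398 gained at 126 cold and 153 control tags and a ratio of 1.11 (0.868 to 1.41). With the cut allowed to lie 1 base to either side, 4 small RNAs passed, namely miR160, miR166, miR169 and miR393.

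**Figure D2:**
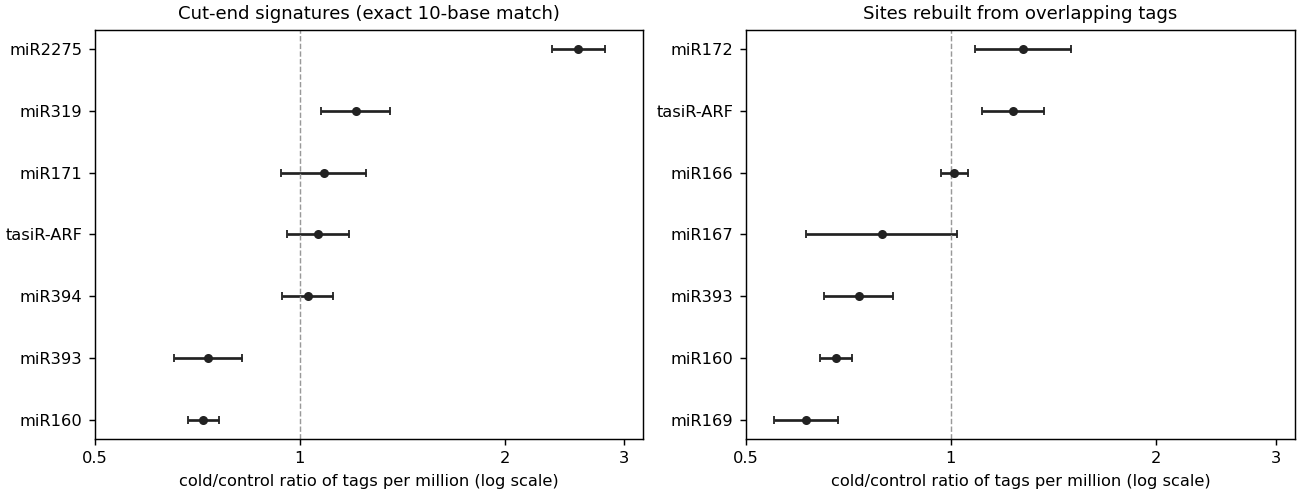
Cold/control ratio of RPM (horizontal axes, log scale) for the small RNAs that passed the rule, by cut ends matched over 10 bases (left) and by sites rebuilt from overlapping tags (right); points are the ratios of 1 library against 1 library, bars their exact 95% intervals for counting error, and the dashed line marks 1. miR2275 lies at 2.57 and the other small RNAs between 0.613 and 1.28. The tags of the miR160 and miR393 sites, and some of tasiR-ARF, are counted in both panels.

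Over all single 5′ ends, more were higher than lower in the cold library. Of 114183 ends with at least 50 tags, 3665 had an interval wholly above 2 and 532 had one wholly below 0.5. A simulation with 1 constant ratio and counting error only gave 0 ends either way. The standard deviation of the log2 ratio across ends was 0.79, against 0.32 in that simulation, and the median was -0.03. The simulation held no PCR duplicates and no variation between samples or library preparations. The excess over it therefore cannot be assigned to the treatment. The ends higher in the cold library had a mean GC content of 42.1% (SD 11.6 across ends), against 48.7% over all ends tested and 50.6% for the lower ends. Of the higher ends, 31.4% overlapped another of them by a shift of a few bases, against 16.3% on average in random sets of the same size. Among the lower ends 18.4% did so, but no random sets of their smaller number were drawn. Whether such overlap was particular to the higher ends was therefore not tested.

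The largest ratios came from ends nearly missing from the control library. The end AACTTCAAAATAACTGAC had 82 cold tags and 0 control tags, so it was at least 36.7-fold higher against the floor of 3 counts, and its exact interval, which also covers the error of the cold count, began at 29.2. The end ACCTGGAGATATCAGAAG had 51 and 0 tags, at least 22.9-fold higher against that floor, with an interval from 17.9. TTACTATGGTCAGTGCAG was counted 351 times against 1, a ratio of 472 (84.1 to 18692). AATACTAGTAGGCGAAAT had 270 and 2 tags, a ratio of 182 (49.8 to 1506). The other 8 of the 12 highest ends had ratios from 95.01 to 191. Among the lowest, TATTGTTGCCCTCTCTGG had 2 cold and 56 control tags, a ratio of 0.0480 (0.00568 to 0.182), and CAATGAAGATAAGCTTTT had 13 and 177 tags, a ratio of 0.0987 (0.0516 to 0.173). The other 10 of the 12 lowest had ratios from 0.0507 to 0.130.

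**Figure D3:**
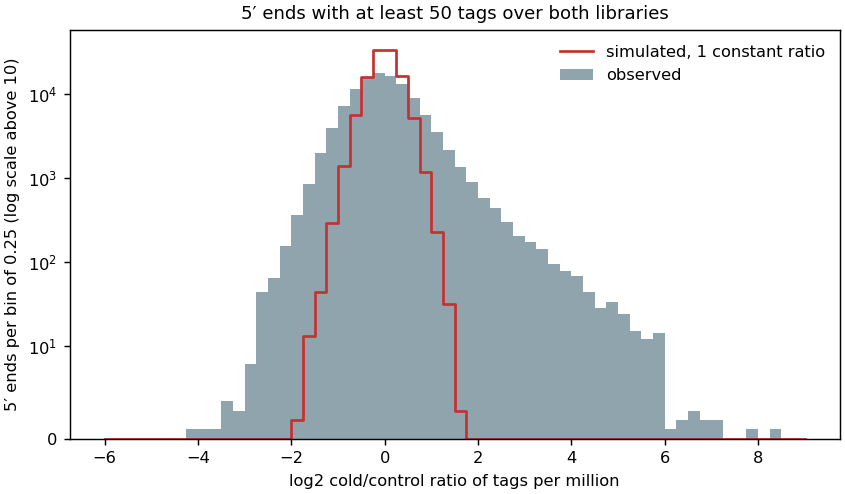
Number of 5′ ends (vertical axis, bins of 0.25, log scale above 10) by log2 cold/control ratio of RPM (horizontal axis), for the 114183 ends with at least 50 tags over both libraries; grey bars are observed and the red line is a simulation with 1 constant ratio. The observed ratios spread more widely than the simulated ones (SD 0.79 against 0.32), with a longer tail towards the cold library. The simulation held counting error only.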

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

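The tests of tags that begin with a small RNA itself were all chosen after the result was seen. Such tags lie outside the cut-end counts, and 5 of the 30 small RNAs had at least 20 of them over both libraries and an interval of the cold/control ratio above 1, which is a signal outside the main measurement and above the control level. Tags that began with the first 18 bases of miR396 were counted 72 times in the cold library and 11 times in the control library, a ratio of 8.80 (4.64 to 18.4). For miR156 there were 22 and 7 tags and a ratio of 4.23 (1.74 to 11.7). The ratio was 3.86 (2.64 to 5.74) for miR167, with 109 and 38 tags. It was 1.73 (1.13 to 2.65) for miR408, with 54 and 42 tags. For miR168, 81 and 66 tags gave 1.65 (1.18 to 2.32). The direction was not shared by the most abundant of these sequences, since miR159 had 1219 cold and 2187 control tags and a ratio of 0.749 (0.698 to 0.804).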

How the results depend on the processing

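Tests of cut ends with the median ratio of ends or with tags of 20 or of 21 bases alone, of rebuilt sites with another minimum or with overlaps seen once, and of single ends were chosen after the result was seen. The leading tag was left out together with all tags of its 5′ end, although the tag alone had been planned. No paired analysis was possible because each condition had 1 library and no test was run. Gene-level tags, gene lists and positions along transcripts, with their alternatives, were not run. The direction of miR2275, at 1.77 to 2.91, and of miR393, at 0.662 to 0.856, held in 9 of 9 alternatives each. Scaling alone shifted the ratios too little to turn either. With each distinct tag counted once, the miR393 ratio was 0.806 with an interval that included 1 (0.437 to 1.45). Scaling and tag length were also tested as explanations of the miR2275 ratio, which was 2.46 when scaled to distinct tags, 2.91 in tags of 20 bases and 2.25 in tags of 21 bases. For miR319 the ratio went to 0.916 with each distinct tag counted once and to 0.913 without the leading end. For miR160 these settings gave 1.13 and 1.34, and of these 4 values only the last had an interval without 1. The cause was not tested for the first setting, and the second left out the end that held most tags. Of 63 alternative ratios of cut ends, 42 stayed within the interval and 17 moved, 4 up and 13 down. Of 26 for rebuilt sites, 25 stayed within it, some with unchanged counts. Named single ends (44 of 44 stayed) and the most abundant tags (12 of 12 moved up) were only rescaled, so interval width set both. The scalings shifted log2 ratios by -0.06 to 0.03.

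Where 7 small RNAs passed by cut ends, 4 passed with 1 mismatch, 3 of them among the 7 and miR166 besides, 0 with each distinct tag counted once, 3 without leading ends and 4 in tags of 20 bases. With bases 2 to 10 matched, 6 passed, 5 of them among the 7, with miR166 gained and miR319 and miR393 lost. Of the 7, 2 were higher in cold, but 1 in tags of 20 bases and 1 in tags of 21 bases, without miR319. miR319 was also replaced by tasiR-ARF with 1 mismatch and with each distinct tag counted once, at 1.06 and 1.46, and by miR160 without leading ends. Lower in cold were 2, but 0 with each distinct tag counted once, 1 without leading ends and 3 with 1 mismatch, where miR394 had 0.888. At a penalty of at most 3, 9 small RNAs had a rebuilt site instead of 22, 6 passed, and without miR172 and miR169 1 was higher and 2 were lower in cold. With the cut window widened by 1 base, 4 passed, and with overlaps seen once 5. Ends over 2-fold higher and lower numbered 7700 and 1550 from a minimum of 20 tags, and 1776 and 210 from 100 tags, where more and fewer ends were tested.

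Among tags of 20 and 21 bases alone, 55.1% of cold and 61.4% of control tags had 20 bases, 44.9% and 38.6% had 21, and 18.7% and 18.3% began with G. With each distinct tag counted once these were 51.0% and 55.6%, 44.6% and 40.9%, and 19.7% and 19.1%. Among tags with at least 2 counts, 54.3% of cold and 39.95% of control sequences were shared, with 77.1% and 68.7% of tags. At equal depth, 38.6% and 36.4% were shared, with 66.8% of cold tags. Of the 23 small RNAs whose cut ends did not pass, 3 had under 20 tags and 20 failed by their shuffles.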

Other observations

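The tests of ribosomal RNA fragments, of a cold response or a stage shift, and of GC bias, plastid and mitochondrial transcripts were chosen after the result was seen, as were the small RNAs named in the next paragraph.

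Beyond the named small RNAs, miR2118, which like miR2275 triggers phased small RNAs in grass reproductive tissue, had 108 cold and 80 control tags at its cut end, a ratio of 1.82 (1.35 to 2.45), and exceeded 90.1% of its shuffles. No site was rebuilt for it at the main settings, and with overlaps seen once allowed its 3 sites went the other way, with 84 and 162 tags and a ratio of 0.697 (0.529 to 0.913). miR156, which targets SQUAMOSA promoter-binding-like factors, had a cut-end ratio of 0.777 (0.657 to 0.918) with 226 and 391 tags, and exceeded 99% of its shuffles but no more, so that it did not pass the rule. Its rebuilt sites had a ratio of 0.874 (0.736 to 1.04). miR396, which targets growth-regulating factors, had a cut-end ratio of 0.646 (0.526 to 0.789) but 3.91 (2.63 to 5.96) over 2 rebuilt sites, and passed by neither. Of these sites, 1 had 87 cold and 23 control tags and the other 12 and 11, and the ratio was 1.23 with the cut window widened by 1 base and 1.62 with overlaps seen once. miR164, which targets NAC transcription factors, had a cut-end ratio of 0.459 (0.290 to 0.707) and a ratio of 0.927 (0.497 to 1.70) at rebuilt sites, and passed by neither.

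miR2275 cut ends were more frequent in the cold library, at a ratio of 2.57 (2.35 to 2.81). The values argue against 1 or a few abundant tags, since without the leading end the lower bound was 2.09 and 90.6% of the ends with at least 10 tags were higher in cold. They also argue against GC content or first base of the tags, since sets matched on count, GC content and first base gave at most 1.56 within their central 95% and 0% of 10000 reached the observed ratio. Pairing beyond the 10 matched bases was not shown for these ends, since no site was rebuilt at the main settings and the few sites of 2 alternatives had ratios of 0.598 and 0.791 with intervals that included 1. A response to cold and a shift in developmental stage of the anthers cannot be told apart, because RNA of 3 stages was mixed within each condition. Neither can be told from a difference between the libraries, because each condition had 1 library.

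A few very abundant ends took a larger share of the cold library, in which the 10 most abundant cold ends made up 2.66% of cold tags and 0.736% of control tags. A different length of tags does not account for this, since among tags of 20 bases alone their share was 3.41 times higher in cold. The ends were chosen by their cold counts, which favours a higher share in cold. Ribosomal RNA fragments are a candidate explanation, since 77.7% of the tags of these ends lay in, or within 4 bases before, the listed stretches of 18S and 5.8S ribosomal RNA. The listed stretches do not cover the whole pattern, since 4 of the 10 ends lay outside them with ratios from 1.75 to 11.5, while the 6 ends inside had ratios from 1.10 to 7.72. Whether the amount of such fragments differed through RNA quality, selection of polyadenylated RNA or the treatment was not tested, so no biological explanation was tested.

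The 2332 ends at least 4-fold higher in the cold library were AT-rich, with a mean GC content 6.62 (bootstrap 95% interval 6.17 to 7.05) percentage points below that of all ends with at least 50 tags. A trend with GC content was present, since 7.79% of ends with 3 to 5 G or C among their 18 bases but 2.06% of those with 9 to 11 were over 2-fold higher. The values argue against a shift of the median ratio with GC content as the whole cause. With the median of ends of equal GC content subtracted, the gap was still 4.88 (4.42 to 5.37) points. It was -0.22 (-0.76 to 0.26) in data simulated with that shift alone, a check of the method whose small gap followed from its design. A bias that widened the spread of AT-rich ends was not tested, nor was the GC content of the longer fragments. Plastid transcripts remained open. The plastid list had a summed ratio of 1.90 and the cytosolic and nuclear list 0.995. They matched 3.22% and 2.70% of the 4-fold higher ends against 0.370% and 6.69% of all ends tested. At equal GC content, the median log2 ratio of plastid ends was 0.793 (bootstrap 95% interval 0.678 to 0.891) above that of cytosolic or nuclear ends. The bootstrap drew single ends and not proteins, so its interval does not measure the spread among plastid transcripts. Of the 1277 plastid ends, RbcL gave 678, AtpB 597 and Rps12 2. However, RbcL had 2.66 and Rps12 2.52 while AtpB had 0.910, and the other 6 plastid proteins had no matching ends. Also, 9 residues do not separate an organelle gene from a copy or a homologue elsewhere. The mitochondrial list decided nothing, since it matched 0 of the 4-fold higher ends and 0 of all ends tested, and its ratio of 2.84 (1.22 to 7.12) came from 19 cold and 9 control tags of ends below the minimum.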
